A study of Mus musculus with 12 samples.

How the data were processed

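Gene counts were analysed from 12 RNA libraries of neonatal mouse cortex (postnatal day 0). Per the labels, the RNA was depleted of ribosomal RNA and the libraries were made by ClickSeq, a method that joins sequencing adapters to randomly terminated cDNA by click chemistry instead of fragmentation and ligation. The groups were taken from the sample labels: 4 libraries labelled control, 4 labelled dKO-N (H3f3a and H3f3b deleted with Neurod6-Cre) and 4 labelled dKO-E (H3f3a and H3f3b deleted with Emx1-Cre). The series' design text also names chromatin and single-nucleus assays, which were not analysed here.

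The deposited values are raw counts per gene, 1 file per library, in whole numbers, with no normalization by the authors. Per the submitters' processing notes, STAR, UMI-tools and HTSeq were used with the mm10 build; their versions and the gene annotation are not given in the sources used here, nor are the counting options. UMIs (unique molecular identifiers) mark single cDNA molecules, so a count stands for a molecule where duplicates were collapsed. Each file held 51912 gene lines and 5 summary lines. The summary lines name no gene and stayed out of library sizes and tests: reads without a feature made up 6.65% to 8.94% of each library, ambiguous reads 2.0% to 2.2% and reads mapped to several places 2.3% to 4.16%, which left 85.2% to 88.9% in genes. Gene names, positions and types were taken from GENCODE M21 (mm10) by gene identifier, which matched 51719 identifiers (99.6%). Whether strand was used in counting is not stated, so overlapping and antisense genes, and genes with near-identical copies such as H3f3a and its pseudogenes, are uncertain. Across 10445 genes, expression correlated with the length of the whole gene (Spearman rho 0.55) more than with exonic length (0.49), and the 100 most abundant genes had a median length of 575.3 kb against 32.2 kb for all, which leaves open that introns were counted.

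Total counts in genes ran from 722080 to 3502017 per library. At these depths 3 counts, taken as the floor, correspond to 0.86 to 4.15 counts-per-million (CPM). Counts were scaled with TMM factors, filtered with edgeR's filterByExpr (minimum count 10), which kept 11076 genes and 99% of the counts, and tested with edgeR's quasi-likelihood test (glmQLFit with robust estimation, glmQLFTest) in 1 fit of all 12 libraries with a term for group and 9 residual degrees of freedom. The common biological coefficient of variation was 10.6%. Adjusted p-values are Benjamini-Hochberg values over the genes tested in a comparison, with a threshold of 0.05. The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 for tables and plots. CPM values are TMM-scaled and given as mean ± SD over 4 libraries, and log2 fold changes are given with their standard error (SE). The labels do not say that the libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical in part. No pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom 1.62 to 6.09), so each was counted as 1 sample.

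The pipeline was tested on simulated counts drawn from the real means and library sizes in 10 draws, each with 200 genes changed per comparison. For dKO-N against control, 44.2% of genes changed 1.5-fold were recovered, 74.2% of those changed 2-fold and 97.7% of those changed 4-fold, with 6.2% false calls on average (3.8% to 10.3% in single draws) among a mean of 10850 genes tested. For dKO-E against control the shares were 49.8%, 81% and 98.1%, with 6.8% false calls (3.8% to 9.2%).

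The design, the alternatives, the rule for named genes and 34 gene lists were fixed before the data were examined. For each comparison the named genes are those with an average log2 CPM of at least 3 that passed the test, had no predicted-model or pseudogene name and did not overlap between groups, 10 with the largest rise and 10 with the largest fall (5 and 5 between the knockouts). H3f3a, H3f3b, Neurod6 and Emx1 are always named, as are up to 4 changed members of each list with the largest fold change. Where no member changed, up to 2 with the highest expression serve as examples. The lists covered chromatin (H3.3 genes, H3.3 chaperones, replication-coupled histones, Polycomb and Trithorax subunits, Hox cluster genes, imprinted genes), cortical neurons (upper-layer, layer 5, layer 6 and subplate neurons, newborn cortical neurons, mature neuron and synapse genes, axon guidance and axon growth), progenitors (radial glia, intermediate progenitors, cell cycle), other cells and regions (cortical interneurons, Cajal-Retzius cells, astrocytes, oligodendrocyte lineage, microglia and macrophages, endothelium and mural cells, meninges, choroid plexus, red blood cells, striatum, thalamus and hypothalamus), and responses or quality (p53 targets and cell death, immediate early genes, interferon response, ribosomal proteins, mitochondrially encoded genes, sex-linked check genes, Cre driver loci). Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, which left 27 lists and 81 tests over the 3 comparisons, adjusted together. Camera asks whether a list's genes moved further in 1 direction than other genes. Calls were repeated with a correlation estimated from the data and with fry. The fry values used ask whether a list's genes moved together in 1 direction, without setting them against other genes. Member counts are given over all tested genes and adjusted over the list alone.

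Per-library levels of cell type lists (mean log2 of CPM plus 1) were compared with two-sided exact permutation tests, for which 4 libraries against 4 cannot give a p-value below 0.029. Similarity between the knockouts, which share their controls, was set beside 50 simulations without any effect and 6 splits of the controls. The alternatives were DESeq2 size factors, library totals, upper-quartile factors, DESeq2, limma-voom, filters on low counts, only the 2 groups compared, a replicate block, sex as a covariate, adjusted p under 0.01 and each library left out. Added after seeing the data were fits without the libraries labelled control 1 and 3, without those labelled dKO-N 1 and 3, and with every library thinned to 722080 counts. Genes near Neurod6, families of related gene names and pairs of neighbouring genes were also tested, with results in the closing part.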

Results

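Histone H3.3 is the variant of histone H3 that is deposited in chromatin outside DNA replication, and in the mouse identical H3.3 proteins are encoded by H3f3a and H3f3b. RNA was measured in neonatal mouse cortex in which both genes were targeted by either of a pair of Cre drivers. Neurod6-Cre acts in new, postmitotic excitatory neurons (dKO-N), and Emx1-Cre acts earlier, in the cortical progenitors that give rise to them (dKO-E). The comparisons ask what changes when H3.3 is deleted after neurons have left the cell cycle, what changes when it is deleted from progenitors onward, and where these differ. The libraries labelled control 1 to 4 held 3083599, 1974975, 2430299 and 1996106 counts in genes. Those labelled dKO-N 1 to 4 held 722080, 1046240, 746318 and 3502017, and those labelled dKO-E 1 to 4 held 1452515, 2401352, 2503581 and 1734417.

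The targeted genes were examined first. H3f3a (chromosome 1, 180800832 to 180813943, mm10) was measured at 17.7, 117, 16.4 and 121 CPM in the libraries labelled control 1, 2, 3 and 4. It was at 36.7, 30.8, 22.1 and 37.8 CPM in those labelled dKO-N, and at 30.0, 28.4, 25.8 and 22.9 CPM in those labelled dKO-E. The libraries labelled control 1 and 3, with 50 and 38 counts, thus lay below every knockout library and went against their label. Group means were 68.0 ± 58.9 CPM in control, 31.9 ± 7.23 in dKO-N and 26.8 ± 3.11 in dKO-E (SD, n = 4). H3f3a did not pass the test in either knockout (log2 fold change -0.96, SE 0.705, edgeR adjusted p = 0.494 for dKO-N, and adjusted p = 0.228 for dKO-E). H3f3b (chromosome 11, 116021912 to 116027962) was at 121, 76.7, 143 and 84.2 CPM in the libraries labelled control 1 to 4. It was at 146, 117, 113 and 111 CPM in dKO-N 1 to 4 and at 170, 176, 180 and 167 CPM in dKO-E 1 to 4. It did not pass the test in dKO-N, at 122 ± 16 CPM (log2 fold change 0.16, SE 0.15, adjusted p = 0.583). In dKO-E it rose to 173 ± 6.1 CPM (log2 fold change 0.69, SE 0.138, adjusted p = 0.000707). Between the knockouts H3f3b was higher in dKO-E (log2 fold change 0.53, SE 0.147, adjusted p = 0.0303). That call was lost when any of dKO-N 2, 3 and 4 or dKO-E 1 to 4 was left out (adjusted p = 0.0544 to 0.24). It was also lost with sex as a covariate (log2 fold change 0.53, adjusted p = 0.137). Only dKO-E 3 and 4 held Y-linked counts, so in that fit dKO-E 1 and 2 alone carry the dKO-E effect. A count over a whole gene does not resolve the deleted part, so these totals do not measure how much of each gene was removed. Neither knockout group was lower in H3f3b, and control 2 and 4 lay below all 8 knockout libraries. Such totals cannot test the labels of the knockout groups. Because of these values, groups are named by their labels throughout and every direction below is one between labels. The main counts are also given without these libraries.

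**Figure D1:**
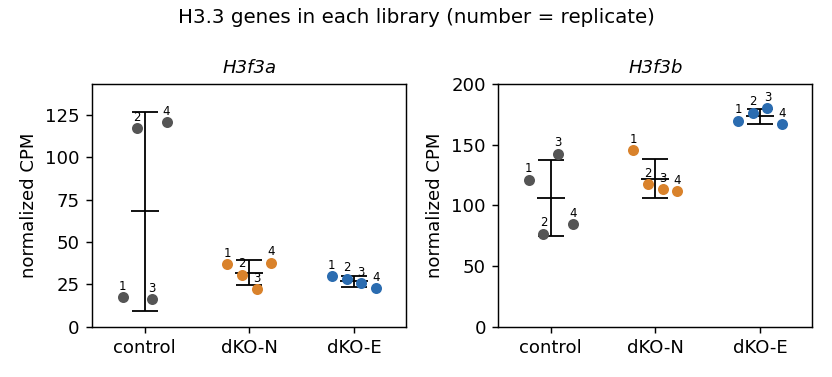
Normalized counts-per-million values (vertical axis) of H3f3a and H3f3b in each of the 12 libraries, by group (horizontal axis), with replicate numbers beside the points; black bars show the mean ± SD of 4 libraries. For H3f3a the libraries labelled control 1 and 3 sit at 17.7 and 16.4 CPM, below all 8 knockout libraries, while control 2 and 4 sit at 117 and 121 CPM.

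The driver genes moved as well. Neurod6, a transcription factor gene of excitatory neurons (chromosome 6, 55677822 to 55681263), fell from 141 ± 9.48 CPM in the libraries labelled control to 58.7 ± 3.90 CPM in dKO-N (log2 fold change -1.27, adjusted p = 1.21e-10). In dKO-E it fell to 71.0 ± 6.47 CPM (log2 fold change -0.98, adjusted p = 2.14e-09), although only dKO-N carries the Neurod6 driver. Emx1 (chromosome 6, 85187438 to 85204462) was measured at 16.8 ± 3.00 CPM in control, 22.9 ± 2.82 in dKO-N (adjusted p = 0.245) and 24.4 ± 5.55 in dKO-E. Its rise in dKO-E only just passed (log2 fold change 0.53, adjusted p = 0.0489) and was lost in 7 leave-outs of a single library (adjusted p = 0.0535 to 0.196). Gm3279, a noncoding RNA gene next to Neurod6 (chromosome 6, 55684571 to 55694574), was chosen after its values were seen. It was measured at 2.76 ± 1.01 CPM in control, 109 ± 13.2 in dKO-N (log2 fold change 5.28, SE 0.237, adjusted p = 7.13e-19) and 1.80 ± 1.5 in dKO-E (adjusted p = 0.482).

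In dKO-N, deletion in postmitotic neurons, the lists of mature neuron and upper-layer genes moved down and the progenitor lists moved up, relative to the libraries labelled control. With an estimated correlation only the mature neuron list of these still passed, as given below. The largest fitted falls were in Scg2, a granin of secretory vesicles (14.8 ± 2.29 to 1.18 ± 1.19 CPM, log2 fold change -3.98, SE 0.467, adjusted p = 4.56e-08), Klhl14 (log2 fold change -3.61) and Ntf3, a neurotrophin (log2 fold change -3.31). Scg2 had fewer than 3 counts in each dKO-N library, Klhl14 in dKO-N 1 to 3 and Ntf3 in dKO-N 2 and 3, so the size of these falls is imprecise. Kcnh1, a potassium channel gene (-2.81), Nr4a2, a transcription factor gene of subplate neurons (-2.81), Gpc5, a glypican (-2.60), the estrogen receptor gene Esr1 (-2.51), Glis3 (-2.44), Il1rap (-2.56) and Nrgn, a synaptic calmodulin-binding protein (-2.44), fell as well. Gpc5 was at 35.1 CPM in dKO-N 4, against 68.1 to 73.1 CPM in the other dKO-N libraries, so the size of its fall leans on that library. The largest rises were in Ttc7 (13.2 ± 1.23 to 156 ± 22.8 CPM, log2 fold change 3.51, SE 0.276, adjusted p = 1.95e-06), Colec12, a scavenger receptor (4.77 ± 1.55 to 44.8 ± 11.4 CPM, log2 fold change 3.10) and Lmcd1 (2.80). Tmem176b (2.75), Tpcn2, an endolysosomal channel (2.58), Cfap61, a ciliary protein (2.32), Chst9 (1.96), Smad6, an inhibitor of BMP signalling (1.79), Prkd1, a kinase (92.6 ± 15.7 to 319 ± 41.9 CPM, log2 fold change 1.79), and Hs3st3b1 (1.75) rose as well. Without control 1 and 3, Hs3st3b1 was no longer called (adjusted p = 0.0619). In all, 1255 of 11076 genes changed, 558 higher and 697 lower, 335 of them at least 2-fold. Without the libraries labelled control 1 and 3 the count was 756, and with every library thinned to 722080 counts it was 766. Leaving out any single control gave 972 to 1058, and no other pair of controls was left out. With library totals in place of TMM 57.8% of the called genes were higher, against 44.5% in the chosen scaling. Of 83 calls of genes named by rule, 59 held whichever library was left out.

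Of 81 list tests 18 passed, and 4 of them with an estimated correlation. Among these lists, mature neuron and synapse genes fell most clearly in dKO-N. Of 49 tested members 28 fell (30 adjusted over the list alone) and 1 rose, the glutamate receptor gene Gria1 (camera adjusted p = 1.32e-13; adjusted p = 0.00476 with an estimated correlation). They included the neurofilament genes Nefl (-1.40) and Nefm (-1.37) and the NMDA receptor subunit Grin2a (-1.19). Of 21 upper-layer neuron genes, 12 fell (14 adjusted over the list alone) and 1 rose, Cdh13 (adjusted p = 4.47e-11; adjusted p = 0.0645 with an estimated correlation). Rasgrf2 was at -1.74 and Nectin3 at -1.32. Intermediate progenitor genes rose (4 of 10, 7 adjusted over the list alone, adjusted p = 0.000251; adjusted p = 0.0645 with an estimated correlation). Insm1, a transcription factor gene of these cells, led them (14.7 ± 4.72 to 46.6 ± 12.3 CPM, log2 fold change 1.56, adjusted p = 2.85e-06). The calls of its other 3 risen members, Tfap2c, Mfng and Rhbdl3, were lost without the library labelled dKO-N 4 (adjusted p = 0.0995, 0.0652 and 0.117). Radial glia genes, those of the neural stem cells, rose as a list as well (5 of 17, 9 adjusted over the list alone, adjusted p = 0.00178; adjusted p = 0.405 with an estimated correlation). Pax6 was at 0.98 and Notch2 at 0.88, while the call of Vim was lost without dKO-N 4 (adjusted p = 0.075). The mean log2 level of the tested members was 5.81 in dKO-N 4, against 5.48 to 5.51 in the other dKO-N libraries.

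Camera also passed 3 further lists in dKO-N, of which the ribosomal list also passed in dKO-E (below). Replication-coupled histone genes, which supply histones during DNA synthesis, moved upward with 2 of 26 members past the test, Hist1h2af (0.89) and Hist1h4d (0.85), also 2 adjusted over the list alone. The call of Hist1h4d was lost when any of control 1, 2 and 3 or dKO-N 1 and 2 was left out (adjusted p = 0.0612 to 0.17). The list's adjusted p was 0.00333 (adjusted p = 0.449 with an estimated correlation), and 0.0858 without dKO-N 2. In dKO-E 4 members were higher, also 4 adjusted over the list alone, though the list did not pass (median 0.45, adjusted p = 0.0718). They were Hist2h2ac (1.30), Hist1h1c (0.78), Hist1h1b (0.73) and Hist1h1d (0.69), of which Hist1h1c was lost in 8 leave-outs and Hist1h1b in 5. Of 75 ribosomal protein genes 5 rose (4 adjusted over the list alone), Rps2 by 0.65 and Rpl34 by 0.58 among them, while the call of Rps3a2 was lost in 11 leave-outs. The list's adjusted p was 0.00451 (adjusted p = 0.678 with an estimated correlation), and 0.11 without control 1 and 0.107 without dKO-N 2. The oligodendrocyte lineage list moved down (adjusted p = 0.00878; adjusted p = 0.284 with an estimated correlation), though not without dKO-N 4 (0.0536). Only Tnr, an extracellular matrix gene that neurons express too, fell among its 10 members, also 1 adjusted over the list alone (660 ± 63.0 to 294 ± 43.3 CPM, log2 fold change -1.19). In dKO-E Lhfpl3 rose (0.81) and Gpr17 (-1.63), Tnr (-1.27) and Pdgfra (-0.71) fell, 1 higher and 4 lower adjusted over the list alone, and the list did not pass (median -0.33, adjusted p = 0.0722). Lhfpl3 was lost in 8 leave-outs and Gpr17 in 5. Between the knockouts neither the histone nor the oligodendrocyte list passed (adjusted p = 0.513 and 0.659).

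In dKO-E, deletion from progenitors onward, the upper-layer, mature neuron and layer 6 lists moved down, relative to the libraries labelled control. The layer 6 call was lost with an estimated correlation (adjusted p = 0.206). The largest fitted falls were in Hcrtr2, an orexin receptor (18.0 ± 2.92 to 1.98 ± 1.67 CPM, log2 fold change -3.34, SE 0.394, adjusted p = 2.85e-08), Nr4a2 (-3.20) and Klhl14 (-3.20). Hcrtr2 had fewer than 3 counts in dKO-E 2 and 3 and Klhl14 in dKO-E 1. Kcnj2, a potassium channel (-2.79), Ntf3 (-2.66), Trpc5, a cation channel (-2.52), Htr1f, a serotonin receptor (-2.46), Npas2, a transcription factor (74.2 ± 5.63 to 13.7 ± 2.26 CPM, -2.46), Slc26a7 (-2.37) and Tec, a kinase (-2.35), fell as well. The largest rises were in Colec12 (4.77 ± 1.55 to 82.0 ± 19.2 CPM, log2 fold change 4.06, SE 0.22, adjusted p = 9.94e-16), Ttc7 (13.2 ± 1.23 to 211 ± 67.4 CPM, 4.00), Itprid1 (8.32 ± 3.29 to 65.5 ± 3.87 CPM, 3.03) and Tmem176b (2.83). Smad6 (2.70), Lmcd1 (2.69), Cfap61 (2.58), Slc24a4 (2.54), Tpcn2 (2.48) and Btg3, an inhibitor of proliferation (2.38), rose as well. In all, 2238 genes changed, 1120 higher and 1118 lower, 461 of them at least 2-fold. The count was 1215 without the libraries labelled control 1 and 3, a fit in which Btg3 was no longer called (adjusted p = 0.0964). Leaving out any single control gave 1699 to 1870, and no other pair of controls was left out. The count was 1232 with every library thinned to 722080 counts and 1325 with sex as a covariate. That covariate leaves dKO-E 1 and 2 alone to carry the dKO-E effect, so the lower count does not test sex. With library totals in place of TMM, 73.9% of the called genes were higher against 50% in the chosen scaling, and the median of all genes moved to 0.135. Of 102 calls of genes named by rule, 77 held whichever library was left out.

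Upper-layer neuron genes fell in dKO-E in 14 of 21 cases (15 adjusted over the list alone), and Cdh13 and Plxnd1 rose (camera adjusted p = 1.62e-20; adjusted p = 0.0113 with an estimated correlation). The library labelled dKO-E 1 had a lower level of upper-layer neuron genes (mean log2 6.71) than the other dKO-E libraries (7.04 to 7.08), and the list also passed without it. Among them were Inhba, which encodes an activin subunit (log2 fold change -2.20), Dok5 (-1.91) and Pou3f1 (-1.61). Mature neuron and synapse genes fell in 26 of 49 cases (28 adjusted over the list alone), again with Gria1 the only one to rise over all genes (adjusted p = 2.42e-09; adjusted p = 0.00476 with an estimated correlation). They included Slc17a7, the vesicular glutamate transporter (-1.49), Lrrtm2, a synaptic adhesion gene (-1.17), and Syt4 (-0.94). Layer 6 genes fell in 9 of 16 cases (10 adjusted over the list alone) and Wnt7b, Nfia and Syt6 rose (adjusted p = 0.00278; adjusted p = 0.206 with an estimated correlation). Foxp2 (420 ± 28.3 to 215 ± 29.6 CPM, -0.98) and the neurotensin receptor gene Ntsr1 (-1.36) were among the falls. Radial glia genes rose in 6 of 17 cases (7 adjusted over the list alone, adjusted p = 0.0059; adjusted p = 0.405 with an estimated correlation), with Notch2 at 0.83. Intermediate progenitor genes rose in 4 of 10 cases (6 adjusted over the list alone, adjusted p = 0.0281; adjusted p = 0.239 with an estimated correlation), with Insm1 at 1.16 and Rhbdl3 at 1.15. This list's call was lost without control 1 and 3 (0.0973) and with library totals (0.0615). Its members Sstr2 and Chd7 lost their calls without control 3 (adjusted p = 0.141 and 0.0584). The radial glia genes Sox9 and Phgdh lost theirs without dKO-E 4 (adjusted p = 0.102 and 0.0647). Other single leave-outs ended these calls as well.

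Ribosomal protein genes moved upward in dKO-E, with 11 of 75 past the test and 11 adjusted over the list alone (adjusted p = 0.0219; adjusted p = 0.713 with an estimated correlation), Rps2 at 0.84 among them. That call was lost without control 1 (0.196), without dKO-E 1 (0.0607) and without control 1 and 3 (0.0973). Imprinted genes, expressed from 1 parental copy, also moved upward (5 of 25, 7 adjusted over the list alone, adjusted p = 0.0333; adjusted p = 0.569 with an estimated correlation). Rasgrf1 was at 1.68, Plagl1, a transcription factor gene (30.7 ± 4.21 to 69.4 ± 7.33 CPM), at 1.17 and Snrpn at 0.54. Leaving out dKO-E 1 (0.148) or control 2 (0.0671) ended the list's call. In dKO-N 1 member, Plagl1, rose (0.83), also 1 adjusted over the list alone, and the list did not pass (adjusted p = 0.647). The library labelled dKO-E 1 also held the highest summed level of meningeal genes, a list that shares Igf2 with the imprinted list (131 CPM, against 53.5 in dKO-E 2 and 15.1 to 31.5 in the others). Igf2 was at 43.1 CPM and H19 at 47.0 CPM in that library.

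**Figure D2:**
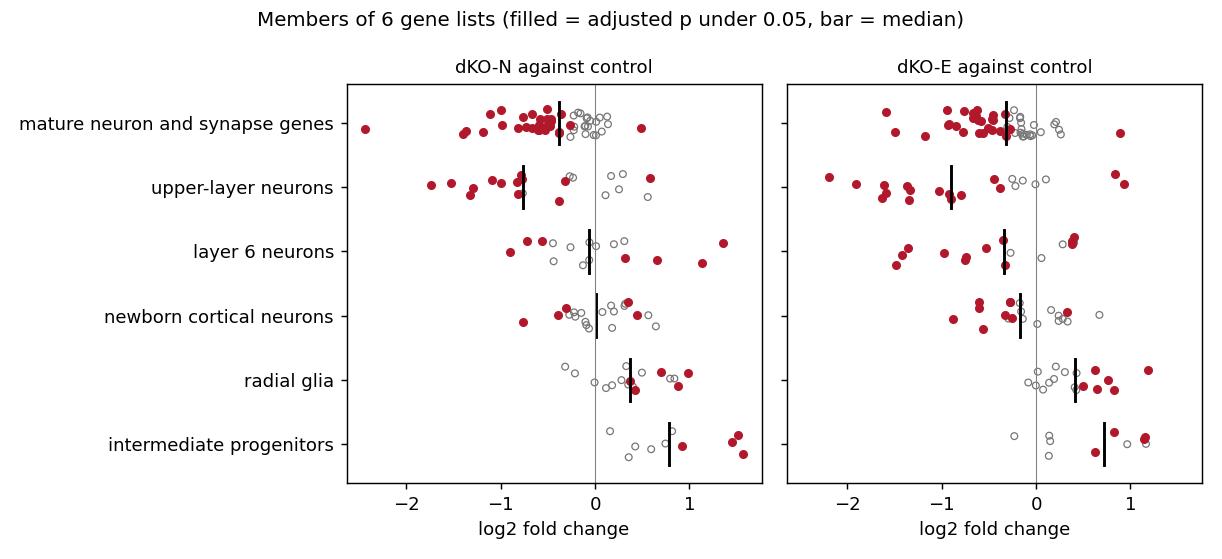
Log2 fold changes (horizontal axis) of the tested members of 6 gene lists in dKO-N (left) and dKO-E (right) against the libraries labelled control; filled points passed an adjusted p of 0.05 over all genes and bars mark list medians. Of the 49 mature neuron and synapse genes 28 fell in dKO-N and 26 in dKO-E, while members of the radial glia and intermediate progenitor lists that passed all rose.

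The knockouts were also compared directly, which asks where dKO-E and dKO-N differ. Driver and time of deletion come together here, and sex differs within dKO-E, so timing alone is not tested. The layer 6 and upper-layer lists were lower in dKO-E than in dKO-N, with 8 of 16 and 9 of 21 members past the test, and the upper-layer call was lost with an estimated correlation (adjusted p = 0.206). Syt6, a layer 6 gene, was measured at 61.1 ± 6.36 CPM in control, 154 ± 24.2 in dKO-N and 80.1 ± 16.2 in dKO-E (log2 fold change between the knockouts -0.95, SE 0.129, adjusted p = 1.86e-05). Tle4, a corepressor of layer 6 neurons, was at 402 ± 33.3 CPM in dKO-N and 250 ± 27.8 in dKO-E (-0.69, adjusted p = 2.01e-05), and Wnt7b at 116 ± 9.74 and 68.9 ± 17.8 CPM (-0.75). The transcription factor gene Pou3f2 was measured at 174 ± 9.83 and 91.2 ± 12.6 CPM (-0.90, adjusted p = 1.33e-06). Of 16 layer 6 genes 8 were lower in dKO-E (10 adjusted over the list alone) and none higher (camera adjusted p = 1.75e-08; adjusted p = 0.0323 with an estimated correlation). Of 21 upper-layer genes 9 were lower (10 adjusted over the list alone) and Lpl, a lipoprotein lipase gene, was higher, though not without dKO-N 4, where Lpl had an adjusted p of 0.0666 (adjusted p = 8.09e-07; adjusted p = 0.206 with an estimated correlation). This call, too, was kept without dKO-E 1, the dKO-E library with the lowest level of the list.

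Scg2 was 6.81 ± 0.891 CPM in dKO-E and 1.18 ± 1.19 in dKO-N (log2 fold change 2.87, adjusted p = 0.000759), a difference that rests on the same low dKO-N counts. Itprid1 (1.44), Prkg2, a kinase (1.53), Cpne8 (1.40) and the axon guidance gene Slit3 (1.40) were higher in dKO-E as well. Itprid1 was at 37.8 CPM in dKO-N 4, against 11.2 to 15.2 CPM in the other dKO-N libraries. Ndnf, a gene of Cajal-Retzius cells and of some interneurons, was lower in dKO-E (28.4 ± 5.21 to 9.30 ± 3.44 CPM, -1.74, adjusted p = 8.82e-06). Also lower were the noncoding RNA Pantr1 (-1.43), Fam151b (-1.25) and the zinc finger genes Zfp975 (-1.15) and Zfp128 (-1.15). Newborn cortical neuron genes moved down (4 of 20, 4 adjusted over the list alone, adjusted p = 0.0414; adjusted p = 0.259 with an estimated correlation), with Nfix at -0.54. Imprinted genes moved up (2 of 25, Meg3 at 0.52 and Mest at 0.65, also 2 adjusted over the list alone, adjusted p = 0.0133; adjusted p = 0.496 with an estimated correlation). The newborn neuron call was lost without dKO-N 1 (0.0778), dKO-N 2 (0.104), dKO-E 1 (0.111) or dKO-E 4 (0.0761), and the imprinted call without dKO-N 1 (0.0577) or dKO-E 1 (0.166). Mest itself was lost in 9 leave-outs (0.0526 to 0.212). In all, 758 genes differed, 345 higher and 413 lower in dKO-E, 121 of them at least 2-fold. This count was 300 without dKO-N 4, 476 without dKO-E 3, 421 without dKO-E 4 and 223 with sex as a covariate. In the fit with sex, dKO-E 1 and 2 alone carry the difference for dKO-E. With library totals 65.4% of the called genes were higher, against 45.5%. Of 50 calls of genes named by rule, 20 held whichever library was left out. Those of Prkg2, Cpne8, Fam151b, Pantr1 and Zfp128 were lost without dKO-N 4 (0.0601, 0.0554, 0.118, 0.148 and 0.176). Pantr1 was lost in 10 leave-outs (0.055 to 0.148) and Slit3 in 8 (0.0501 to 0.0728), and Zfp128 in 4 in all.

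**Figure D3:**
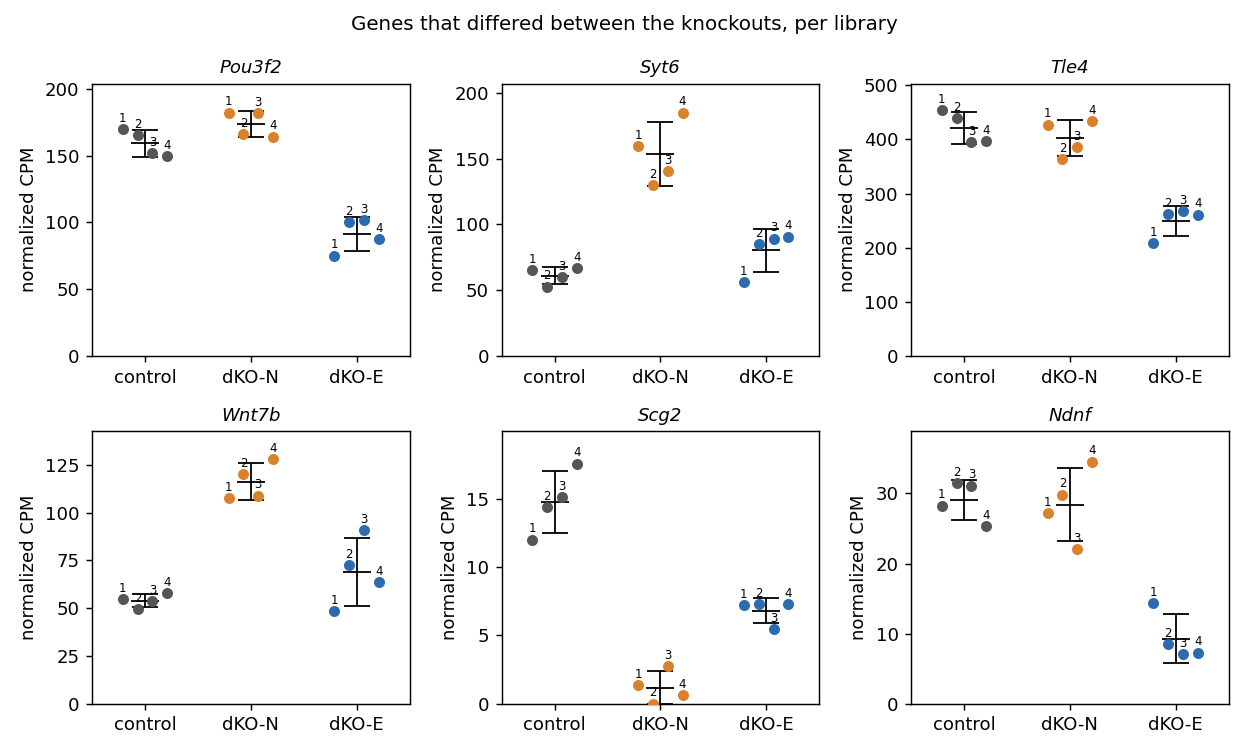
Normalized counts-per-million values (vertical axes) of Pou3f2, Syt6, Tle4, Wnt7b, Scg2 and Ndnf in each library, by group, with replicate numbers beside the points and bars showing the mean ± SD of 4 libraries. Pou3f2 is at 174 CPM on average in dKO-N and 91.2 in dKO-E, and Scg2 at 1.18 CPM in dKO-N and 6.81 in dKO-E.

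Most genes that fell in dKO-N also fell in dKO-E. Of 697 genes lower in dKO-N, 507 were lower in dKO-E too (72.7%, against 70.4 genes for independent lists), and of 558 higher genes 327 were higher too (58.6%, against 56.4). Those reference values leave out that both comparisons use the same controls. In 6 splits that gave each knockout 2 controls of its own, a test added after seeing the data, 292 to 335 genes were lower in both, 8.77 to 11.8 times the number for independent lists. In the same splits 148 to 167 were higher in both, 7.2 to 11.5 times that number. Only Igfbpl1, named after its values were seen, was called in opposite directions (log2 fold change 0.46 in dKO-N and -0.52 in dKO-E). Among the 507 shared falls, 52 went further in dKO-E by the direct test, 14 further in dKO-N, and for 441 no difference passed. Across genes, which are not independent replicates, the fold changes of the knockouts correlated (Pearson's r 0.659, Spearman's rho 0.546). They share their control libraries, which alone gave r = 0.446 in simulations without effects. With the controls split between the comparisons r was 0.511 on average. The covariance of the fold changes was 0.144 against 0.024 in those simulations.

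**Figure D4:**
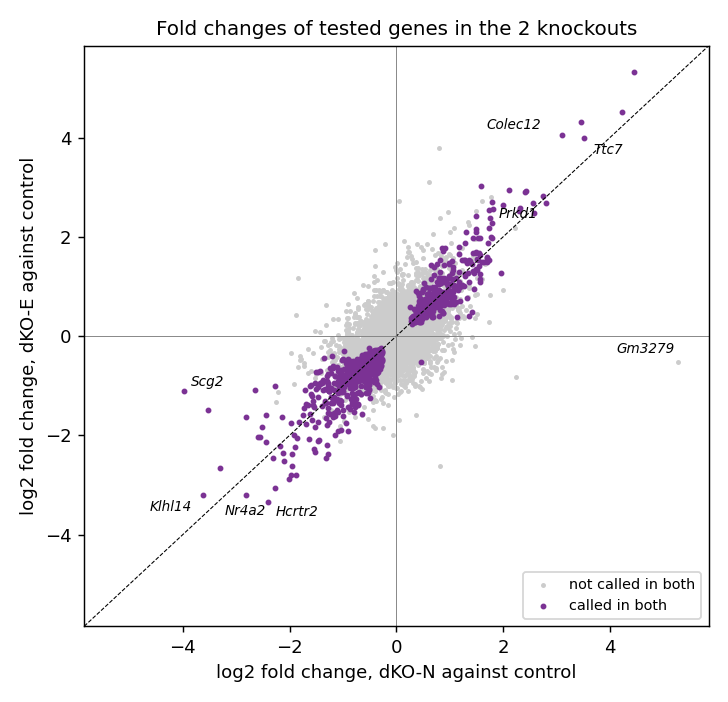
Log2 fold changes of the tested genes in dKO-N (horizontal axis) and dKO-E (vertical axis) against the libraries labelled control; purple points passed the test in both comparisons and the dashed line marks equal change. The 507 shared falls lie at lower left, the 327 shared rises at upper right, and Gm3279 stands alone at right, with log2 fold changes of 5.28 and -0.53.

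Lists of neuronal genes that did not pass camera in a given comparison with control still held genes that moved. Among all tested genes 11.3% were called in dKO-N and 20.2% in dKO-E, and long genes more often. In dKO-N 5% were called in the shortest quartile of gene length and 25.5% in the longest. In dKO-E these shares were 10.1% and 37.5%. The member counts below were not set against genes of like length. Of 19 layer 5 genes 4 rose and 5 fell in dKO-N (5 and 5 adjusted over the list alone), with Cntn6, a cell adhesion gene, at -1.98 and Crym at 1.27. In dKO-E 5 rose and 7 fell (6 and 7 adjusted over the list alone), with Etv1 at -1.03 (adjusted p = 0.123 and 0.119 for the list). Of 8 subplate genes 2 rose and 3 fell in dKO-N and 3 rose and 3 fell in dKO-E, with the same counts adjusted over the list alone (adjusted p = 0.0747 and 0.386). Of 57 axon guidance and axon growth genes 7 rose and 12 fell in dKO-N (9 and 14 adjusted over the list alone), with the ephrin gene Efna5 at -1.46 and Slit1 at 0.97. In dKO-E 13 rose and 15 fell (15 and 16 adjusted over the list alone; adjusted p = 0.876 and 0.363). Of 7 immediate early genes 3 fell and Ier5 rose (1.70) in dKO-N (5 and 2 adjusted over the list alone). In dKO-E 5 fell and Ier5 rose by 1.58 (5 and 2 adjusted over the list alone; adjusted p = 0.168 and 0.0873). Of these, Dusp6 was lost in dKO-N without dKO-N 4 (0.171), and in dKO-E Nptx2 was lost in 8 leave-outs and Dusp6 in 3. Layer 6 genes did not move together in dKO-N (4 rose and 3 fell, 4 and 4 adjusted over the list alone, adjusted p = 0.647; median -0.06, mean 0.02). Syt6 rose there by 1.35 and Wnt7b by 1.13. Of 20 newborn neuron genes 2 rose and 3 fell in dKO-N (3 and 3 adjusted over the list alone, adjusted p = 0.872; Mllt11 was lost without dKO-N 4 and Sox4 without control 2 or dKO-N 2), and 1 rose and 8 fell in dKO-E (3 and 8 adjusted over the list alone, adjusted p = 0.13). The median and the test also differed in sign for axon guidance, newborn neuron, striatal and p53 genes in dKO-N and for subplate, chaperone, microglial and mitochondrially encoded genes in dKO-E. Between the knockouts they differed for layer 5, radial glia, endothelial and thalamic genes.

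The following lists of other cells, cell states and chromatin factors did not pass camera in either knockout. Among all tested genes, 11.3% were called in dKO-N and 20.2% in dKO-E. Of 20 cortical interneuron genes, Npy, a neuropeptide, fell (-1.89 in dKO-N, -2.23 in dKO-E). Counts were 1 higher and 1 lower in dKO-N and 1 and 2 in dKO-E, also adjusted over the list alone (list adjusted p = 0.584 and 0.647). Of 8 Cajal-Retzius genes none passed in dKO-N, where Reln was measured at 403 ± 47.4 CPM against 400 ± 32.0 (adjusted p = 0.996 for the list). In dKO-E Reln (-0.59) and Ndnf (-1.69) fell and Ebf3 rose (0.93), 3 lower and 1 higher adjusted over the list alone (adjusted p = 0.322). Astrocyte genes held 1 of 14 higher in dKO-N and 3 in dKO-E, with Aldh1l1 at 0.89, and the same adjusted over the list alone (adjusted p = 0.357 in both). Cell cycle genes held 2 of 23 higher in each knockout, also adjusted over the list alone, with Hmgb2 at 0.67 in dKO-E (adjusted p = 0.0669 and 0.295). The p53 and cell death list held 3 and 4 of 12 higher, also 3 and 4 adjusted over the list alone, where 1 was lower in dKO-N, with Mdm2 at 0.57 and Ckap2 at 1.52 in dKO-E (adjusted p = 0.728 and 0.317). Of 13 H3.3 chaperone genes Dek (0.61) and Asf1a (0.62) rose in dKO-E and Cabin1 fell narrowly in dKO-N (-0.31, adjusted p = 0.0479; 0 adjusted over the list alone; list adjusted p = 0.475 and 0.582). Of 24 Polycomb and Trithorax genes Kdm6a rose in dKO-N and Jarid2 fell in dKO-E, each with 0 adjusted over the list alone (list adjusted p = 0.599 and 0.862). Without dKO-N 4 the p53 list's calls in dKO-N were all lost, Trp53inp1 (0.108), Sesn1 (0.304) and Ckap2 (0.548), as were those of the cell cycle genes Rrm2 (0.311) and Cenpf (0.388) and of the astrocyte gene Slc4a4 (0.115). Rrm2 was lost in 6 leave-outs, Ckap2 in 9 and Trp53inp1 in 5. In dKO-E Trp53inp1, Tacc3 and Id4 were lost in 5 leave-outs each, Slc4a4 in 6 and Bcl2l11 in 2. Other calls that did not hold when single libraries were left out included Cabin1 in 10 leave-outs (up to 0.15), Kdm6a in 6 (up to 0.227), Jarid2 in 5 (up to 0.185) and Asf1a in 2 (up to 0.0799).

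No tested list of a tissue next to the cortex passed camera. Striatal genes held 1 higher and 2 lower of 7 in dKO-N (2 and 2 adjusted over the list alone), with Meis2 at 0.49 and Rgs9 at -0.90, and 2 lower in dKO-E (3 adjusted over the list alone; adjusted p = 0.723 and 0.322). In dKO-N thalamic and hypothalamic genes held 1 higher and 1 lower of 6, also adjusted over the list alone, and in dKO-E 1 higher, Lef1, at 1.71 (adjusted p = 0.551 and 0.329). The calls in dKO-N were lost without dKO-N 4, Lef1 at 0.271 and Rora at 0.075, and Rora in 4 leave-outs in all. Of 12 endothelial and mural genes none passed in dKO-N and Rgs5 fell in dKO-E (-0.68; 0 adjusted over the list alone; list adjusted p = 0.317 and 0.338). Of 3 microglial genes Csf1r rose in dKO-E (1.36; list adjusted p = 0.386 and 0.611), and red blood cell genes held none of 3 (adjusted p = 0.888 and 0.584). Of 14 mitochondrially encoded genes only mt-Co3 passed, in dKO-E (0.90; 0 adjusted over the list alone; list adjusted p = 0.838 and 0.989). The call of Rgs5 was lost in 3 leave-outs (0.0788 to 0.144) and that of mt-Co3 in 5 (0.0564 to 0.0841). The Hox list had 0 tested members, the choroid plexus list 1, with Enpp2 (adjusted p = 0.808 and 0.417), and the meninges list 2, with Igf2 (0.953 and 0.271) and Islr (0.756 and 0.934). The interferon list had 2, with Stat2 (0.907 and 0.702) and Ifit2 (0.64 and 0.676), and the sex-linked list 1, Xist, so none of these was tested as a list. Over all members with counts, the mean log2 level of meningeal genes was 3.12 and 2.21 in dKO-E 1 and 2, against 0.911 to 1.55 in the other libraries (dKO-E minus control 0.781, exact permutation p = 0.314, adjusted p = 0.628). Levels in dKO-E exceeded those in control by 0.462 for thalamus and hypothalamus and by 0.615 for choroid plexus (exact permutation p = 0.0286, adjusted p = 0.196 for each). The H3.3 and driver lists, of 2 genes each, are given above. Between the knockouts, none of these lists passed (lowest adjusted p 0.101, Cajal-Retzius cells).

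Per-library levels were set beside these changes. The mean log2 level of radial glia genes was 4.69 ± 0.122 in control, 5.01 ± 0.164 in dKO-N and 5.05 ± 0.109 in dKO-E. That of intermediate progenitor genes was 2.91 ± 0.144, 3.57 ± 0.17 and 3.44 ± 0.082. For both lists the exact permutation test gave p = 0.0286 (two-sided, for each knockout against control, the smallest that 4 libraries against 4 allow, adjusted p = 0.196, n = 4). No cell type list passed after adjustment. The 10 most abundant genes took 6.10% ± 0.216 of counts in control, 5.48% ± 0.222 in dKO-N and 4.95% ± 0.129 in dKO-E (exact permutation p = 0.0286, adjusted p = 0.172, n = 4). Xist, the noncoding RNA of the inactive X chromosome, was measured at 1190 ± 59.4 CPM in control and 1380 ± 136 CPM in dKO-N but at 0.782 and 2.24 CPM in dKO-E 3 and 4. These also held counts of Y-linked genes, so sex differed within dKO-E and not within the other groups. Libraries dKO-N 1 and 3, the shallowest, stood apart from the others on the second and the third principal components, and without them dKO-N against control gave 1189 genes.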

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

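The counts of other splits of the libraries were planned before the results were seen, and all other tests in this part were chosen after. In 228 groups of 4 libraries, 13 held a library set apart from the other 3 by more than Dixon's 95% critical value; chance gives about 1 in 20 groups, or 11.4 here. The library labelled dKO-N 4 held 3.5 M (mega) counts, against 0.72 to 1.05 M in the others of its group. It also lay apart in the levels of radial glia genes (5.81, others 5.48 to 5.51) and striatal genes (6.84, others 5.92 to 6.05), in Gpc5 (35.1 CPM, others 68.1 to 73.1) and in Itprid1 (37.8 CPM, others 11.2 to 15.2). List levels here are over members that passed the expression filter. Over all members with counts, as in the report, dKO-N 4 was not set apart by this measure in radial glia genes (5.23, others 4.87 to 5.05) or striatal genes (3.97, others 3.18 to 3.39). The library labelled dKO-E 1 lay apart in the levels of imprinted genes (6.66, others 6.19 to 6.26) and upper-layer genes (6.71, others 7.04 to 7.08). The library labelled control 1 lay apart in axon guidance genes (7.61, others 7.57 at most), Zfp128 (16.6 CPM, others 7.99 to 8.64) and Zfp975 (28.6 CPM, others 20.7 to 21.2). Single values stood apart for Scg2 in dKO-E 3 (5.47 CPM, others 7.18 to 7.29) and for Hcrtr2 in control 2 (22.4 CPM, others 16.2 to 16.8) and dKO-N 1 (listed at 0, others 3.73 to 4.14 CPM).

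Y-linked genes, which no comparison uses, were counted in dKO-E 3 and 4 above the level of every library labelled control. Ddx3y was at 74.2 and 23.5 CPM, Eif2s3y at 85.6 and 38.0, Kdm5d at 52.8 and 24.1 and Uty at 192 and 67.7, against at most 0, 0.533, 0.533 and 1.03 CPM in control.

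H3f3a was low in the libraries labelled control 1 and 3. A knockout library under a control label is argued against: on an axis from the other controls (0) to the knockout libraries (1), over genes called without it, control 3 lay at 0.103 (686 genes) and control 1 at 0.048 (699 genes). H3f3b ran the other way among the controls, at 121 and 143 CPM in control 1 and 3 against 76.7 and 84.2 CPM in control 2 and 4. A loss of reads to H3f3a pseudogenes stays open, because reads mapped to several places were not counted in any gene. The 3 pseudogenes held 2 counts in control 1 and 3 and up to 5 counts each in control 2 and 4, all near the floor. Reads mapped to several places made up 2.3% and 2.7% of control 1 and 3. That share was 2.92% and 2.74% in control 2 and 4. H3f3a ran from 16.4 to 121 CPM among the controls, a gap too small to show in these shares. They therefore do not test a loss of H3f3a reads. The labels do not detail the genotype of the controls, which stays open, and no biological explanation was tested.

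Gm3279, next to Neurod6, was high in dKO-N alone. Loss of both H3.3 genes whichever driver deletes them is argued against, since its log2 fold change in dKO-E was -0.53 (SE 0.475). The altered Neurod6 locus stays open and was not tested, since the driver and the time of deletion come together in this design. A wider stretch of foreign sequence cannot be told apart from chance, because 9 of 71 genes within 10 Mb differed between the knockouts (12.7% against 6.8% elsewhere, odds ratio 1.99, 0.87 to 4.05, Fisher's exact p = 0.0582). Called genes were more frequent in that window against control too, with 16 of 71 in dKO-N (22.5% against 11.2% elsewhere, odds ratio 2.3, adjusted p = 0.0105). In dKO-E, which has no Neurod6 driver, it was 25 of 71 (35.2% against 20.1%, odds ratio 2.16, adjusted p = 0.00843), so the higher share there was also seen without the driver.

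Progenitor markers were higher in both knockouts than in the libraries labelled control. A lower share of neurons as the only cause would raise every other cell type alike. The endothelial genes argue against it, and the microglial genes do not. A part of such a lower share in the rise is not excluded. Progenitor levels rose by more than the mean of 6 other cell types, by 0.55 (SE 0.06) in dKO-N and 0.52 (SE 0.1) in dKO-E, higher in 4 of 4 libraries each. That mean does not test the explanation by itself, since it includes interneurons and Cajal-Retzius cells, which are neurons. It also includes the oligodendrocyte lineage list, in which Tnr, which neurons express too, fell. The types moved apart: interneuron genes changed by 0.06 (SE 0.06) and -0.1 (SE 0.1) and endothelial genes by -0.3 (SE 0.07) and -0.26 (SE 0.14). Microglial genes, with 3 members tested, rose by 0.38 in each (SE 0.14 and 0.13), about as much as radial glia genes (0.31 and 0.39). The progenitor change exceeded the endothelial change by 0.82 (SE 0.07) in dKO-N and 0.72 (SE 0.13) in dKO-E. It exceeded the microglial change by only 0.14 (SE 0.13) and 0.09 (SE 0.12). Astrocyte genes rose by 0.18 (SE 0.07) and 0.21 (SE 0.12). The other cell types were widened from 3 to 6 after a first result was seen. More dividing cells may contribute and cannot be told apart from other causes, since progenitor levels exceeded the change of the cell cycle list by 0.3 (SE 0.09) in dKO-N and 0.25 (SE 0.06) in dKO-E, and other cycling cells share those genes. A direct effect of H3.3 loss on these genes stays open and was not tested.

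The number of changed genes was reached by 1 of 35 splits in each comparison, the real one. It was 1255 for dKO-N against control (highest other 1) and 2238 for dKO-E against control (highest other 0). Between the knockouts it was 758 (highest other 6). This does not exclude chance, since 35 splits cannot give a share below 0.029. The other splits also mix the labelled groups, which adds any group difference to the spread and lowers their counts. For the number of lists, the splits do not decide whether chance is enough. In dKO-N 7 lists were matched or passed in 8 of 35 splits, the real one included (highest other 9). In dKO-E 7 were matched or passed in 10 (highest other 8). Between the knockouts 3, adjusted within that comparison, were matched or passed in 21 (highest other 12). Against control, the highest other counts came from splits that keep 3 libraries of a group together. Such splits keep part of the group difference, so lists can pass in them because of it. Between the knockouts the 12 lists came from an evenly mixed split, with dKO-N 1 and 2 beside dKO-E 2 and 3.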

How the results depend on the processing

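The fits without the libraries labelled control 1 and 3, without those labelled dKO-N 1 and 3 and with every library thinned to 722080 counts were chosen after seeing the data; the other alternatives were planned. No result given in the report reversed, though 1 called gene in each comparison with control had the opposite sign when thinned, and the balance of higher and lower genes turned in dKO-N and between the knockouts under library totals, given below, and between the knockouts also with no filter on low counts (403 higher and 342 lower). In dKO-E, at 1120 higher and 1118 lower, it fell on either side across the alternatives. Genes changed in dKO-N numbered 1255, and 730 at an adjusted p under 0.01, 756 without control 1 and 3 and 766 when thinned. In dKO-E they numbered 2238, and 1325 with sex as a covariate, 1297 at an adjusted p under 0.01, 1215 without control 1 and 3 and 1232 when thinned. Between the knockouts they numbered 758, and 488 with only the 2 groups compared, 500 with a replicate block, 223 with sex as a covariate, 249 at an adjusted p under 0.01 and 324 when thinned. A stricter threshold lowers such counts by construction. With sex as a covariate dKO-E 1 and 2 alone carry the dKO-E effect, so those lower counts do not test sex. No pair of controls other than 1 and 3 was left out. For the others the cause was not tested. The difference of H3f3b between the knockouts was no longer past the threshold with sex as a covariate (0.53, adjusted p = 0.137). Nor was it without dKO-N 1 and 3 (0.61, adjusted p = 0.0597). The adjusted p was 0.000391 to 0.0332 under the other alternatives that keep every library. In the leave-outs that lost the call it was 0.0544 to 0.24. Each fit that lost the call left, in effect, fewer libraries to carry the difference, and the cause was not tested. H3f3a and H3f3b were not retested without control 1 and 3, which were singled out on H3f3a. Named gene calls numbered 235, and 150 when thinned. List tests past the threshold numbered 18, 4 with an estimated correlation and 21 with fry in place of camera. With fry 4 list calls were lost, the histone list in dKO-N (fry adjusted p = 0.0532) and the ribosomal list in dKO-N (0.134) among them. Another 7 were gained, among them layer 5 in dKO-N (0.00115) and dKO-E (0.000562) and p53 and immediate early genes in dKO-E (0.00683 each). The similarity of the knockouts was 0.659, and 0.593 with genes of at least 1 CPM in 4 libraries, which adds low genes, and 0.511 with the controls split. Leaving out each library in turn gave 972 to 1298 genes in dKO-N, 1699 to 2753 in dKO-E and 300 to 1036 between the knockouts, 187 to 222 named calls and 15 to 21 lists. For H3f3a it gave -1.32 to -0.52 in dKO-N, -1.64 to -0.84 in dKO-E and -0.41 to -0.16 between the knockouts, and for H3f3b 0.03 to 0.33, 0.57 to 0.86 and 0.48 to 0.61. The replicate block gave 1065 and 1974 genes against control, 207 named calls and 18 lists; the numbers do not pair the libraries, since 12 correlations between same-numbered libraries ran from -0.124 to 0.013 and 0 libraries correlated best with their own number. Under library totals the higher and lower genes numbered 760 and 554 in dKO-N, 1988 and 701 in dKO-E and 513 and 272 between the knockouts, with a median shift of 0.135 in dKO-E. Among results with lists and named genes included, 68 lost their call without control 1 and 3, 57 with sex as a covariate, 48 without dKO-N 4 and 3 with DESeq2 size factors. List tests were not repeated when thinned, under DESeq2 or under limma-voom, where 51, 38 and 15 of fewer results lost theirs. Depth limits small changes: 3 counts are 4.15 CPM in the shallowest library.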

Other observations

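The tests of neighbouring genes were planned before their results were seen, and those of gene families were chosen after. Ttc7 and 4833418N02Rik, a noncoding gene chosen after its values were seen, start 72 bp apart on opposite strands and rose together. The latter went from 1.89 ± 0.645 to 39.3 ± 9.03 CPM in dKO-N (log2 fold change 4.22, adjusted p = 3.13e-12) and 44.3 ± 11.9 CPM in dKO-E (adjusted p = 2.59e-14). The hypothesis that genes starting head to head move together was tested over 454 pairs within 1000 bp. Fold changes correlated weakly across pairs, which are not independent replicates (Spearman's rho 0.065, permutation p = 0.164 in dKO-N, and 0.078, p = 0.0962 in dKO-E). Pearson's r, which was not tested, was 0.16 in dKO-N and 0.176 in dKO-E. Where both genes of a pair were called, 3 of 3 pairs in dKO-N and 11 of 14 in dKO-E moved the same way. These values leave the hypothesis open.

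Families of related gene names were tested after the Cacna genes, which encode calcium channel subunits, drew notice. Of 531 tests over 177 families with at least 8 members, 9 passed, and 0 with an estimated correlation. In the Cacna family 7 of 11 members fell in dKO-N (median -0.36, adjusted p = 1.59e-05) and 8 in dKO-E (median -0.45, adjusted p = 0.00599), with negative medians under every scaling, but the adjusted p with an estimated correlation was 0.881 and 0.996, so a fall of the family as a set stays open.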
